A study of Mus musculus with 7 samples.

How the data were processed

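Cells of P0 mouse hippocampus were dissociated with trypsin and cultured on poly-D-lysine coverslips, per the labels' protocols, and 10x single-cell 3' v2 libraries were made at DIV1 (1 library) and at DIV3, DIV5 and DIV7 (2 libraries each). The deposited matrices hold UMI counts per gene and cell barcode, 1 matrix per library, without normalization; per the file headers they are integer matrices written by software version 3.0.2, and per the submitters' processing notes reads were processed with Cell Ranger 4.0.0 against mm9. Of 31053 genes 31011 (99.9%) have an identifier in GENCODE M21, an annotation of another build, so no coordinates are given. Identifiers and symbols are those of the deposited files, and 71 duplicated symbols were kept apart by identifier.

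The libraries (DIV1, DIV3 replicates 1 and 2, DIV5 replicates 1 and 2, DIV7 replicates 1 and 2) hold 4192, 5401, 3009, 4610, 4112, 3647 and 3875 barcodes, 28846 in all, and 36226566, 114119537, 47830405, 63181816, 41675548, 44341738 and 38735834 UMIs. Their median UMIs per barcode are 6988, 19595, 13926, 12992, 8751, 11793 and 9681, and their median detected genes 2506, 4542, 3817, 3814, 2931, 3700 and 3091. Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. In DIV7 replicate 1 the mitochondrial limit removed 17.7% of barcodes, and in the other libraries 1.38% to 5.90%. Scrublet (scanpy 1.11.5), run per library at an expected rate of 0.8% per 1000 barcodes, called 169 of 28777 scored barcodes (0.587%) as doublets, under the expected 2.40% to 4.30%, so removal of the top scores at the expected rate (975 cells) was added as an alternative. After these filters 4057, 5068, 2824, 4276, 3859, 2953 and 3511 cells remained.

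Counts were scaled per cell and log-transformed, and 2000 highly variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 gave 24 clusters (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, pandas 2.3.3; random seed 1). Several graph settings were tried, and the naming rule and its thresholds were set, after looking at the clusters and before any gene test; the choice was judged by whether cells with Gad1 and Gad2 formed a cluster and by class sizes. A cluster was named X-like where its score over the marker list of a class was at least 0.25 and 1.25 times the next class's, at least 3 markers were detected, and no other class had more markers among its top 10 genes by fold (10 CPM added). Clusters with at least 3 cycling markers among their top genes were called cycling. A marker counted with at least 50 CPM in its highest cluster. Glutamatergic neuron-like clusters were 5 (Prox1, Neurod1), 7 (Cck, Stmn2) and 10 (Grp, Neurod6), GABAergic neuron-like cells were cluster 18 (Sst, Npy, Gad2, Gad1), and radial glia or astrocyte-like clusters were 2 (Slc1a2, Scd1), 6 (led by Lcn2 and the interferon genes Ifit3 and Isg15), 9 (Hes5, Vgf), 17 (Rgs5, Padi2) and 23 (Glycam1, Aldoc). Clusters 1 (Wisp2, C1ql3) and 22 (haemoglobin and endothelial genes, 185 of its 187 cells from DIV1) stayed unnamed.

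Counts were summed per library over the cells of a class, with at least 20 cells required, and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, a mean per day in 1 fit over all 7 libraries, robust quasi-likelihood F tests with 3 residual degrees of freedom, two-sided, and Benjamini-Hochberg adjusted p under 0.05. Differences between classes used both class sums with the library as a block. CPM are counts relative to the library's total after TMM scaling. Values of a class over all days pooled, percents of another class's level, and the interferon gene values and sums use total counts without TMM. Camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2) tested 26 gene lists and 8 to 15 marker lists per comparison with at least 5 detected genes, adjusted over the lists of a comparison, and again with an estimated correlation. The estimate rests on 3 residual degrees of freedom and gave no call in any comparison, so its outcome decides little about a list. Shares of cells were tested against day by exact two-sided permutation of Pearson's r and Spearman's rho. Groups, tests, marker lists, gene lists and the rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls of the main comparison and 5 of each in the others. These are among genes past the test with a mean of at least 20 CPM and every library of one day above every library of the other, leaving out predicted, haemoglobin, ribosomal and mitochondrially encoded genes. It also names textbook genes and list members with the smallest p. Some genes that the rule names are not reported here.

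A gene was called far higher in another class where that class was at least 4 times higher over all libraries pooled. For neuron sums the other classes were radial glia or astrocyte, ciliated, microglia, fibroblast, oligodendrocyte and choroid plexus cells. For glial sums they were both neuron classes and the same classes without glia. Unnamed, cycling, mural, Cajal-Retzius and progenitor cells were not compared. Folds against 0 counts use a floor of 3 counts over the day; with 1 to 3 counts the ratio of counts has an exact interval at 95%. On counts simulated from the glutamatergic sums, DIV7 against DIV3, the same steps recovered 27.8% of genes changed by a log2 fold of 1 and 71.9% of those changed by 2, and called 16 of 12717 unchanged genes (12910 genes run). These false calls stood beside 27 and 69 recovered genes. For GABAergic sums 10.9% and 62.9% were recovered (7830 genes), with 4 of 7641 unchanged genes called. For radial glia or astrocyte sums 6.12% and 62.6% were recovered (13363 genes). There 15 of 13166 unchanged genes were called beside 6 and 62 recovered ones. For the glutamatergic minus GABAergic difference 1% and 36% were recovered, and for the glial difference 0% and 33%. These called 5 and 6 unchanged genes. Genes, libraries and classes were simulated independently, so the values do not cover differences that genes, same-numbered replicates or the classes of a library share.

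Alternatives were RLE size factors or total-count scaling, DESeq2 1.42.0, no low-count filter or a mean of at least 20 CPM, the replicate number as a block, only the libraries of the days compared, each library left out, thinned sums, doublets kept, a looser (200 genes, no mitochondrial limit) and a stricter cell filter (1000 genes, 5%), Leiden resolution 0.5 and 2, and all neuron-like clusters summed. Chosen after seeing the data were the removal of top doublet scores, a graph without edges under 0.0667, pyramidal-like or dentate-like clusters alone, a wider glia class, leaving out genes far higher in another class (and the factor of 4), and leaving out GABAergic cells with at least 3 UMIs of 4 glutamatergic genes.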

Results

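Single-cell RNA was counted in primary cultures of hippocampal cells taken from newborn mice, in which neurons, glia and other cells of the dissected tissue grow together in a dish. The series title gives synapse formation as its subject, and the cultures were sampled at 1, 3, 5 and 7 days in vitro (DIV). DIV1 has 1 library and DIV3, DIV5 and DIV7 have 2 each, 7 in all. The libraries hold 3009 to 5401 barcodes with 36226566 to 114119537 unique molecular identifiers (UMIs) in total, and the median barcode has 6988 UMIs in the DIV1 library and 19595 in DIV3 replicate 1, the lowest and the highest. After filters and removal of predicted doublets 26548 cells remained. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical. Binomial intervals cover counting error only.

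Glutamatergic neuron-like cells made up less of the cultures with time. Their share of cells was 34.6% in the DIV1 library (exact binomial 95% interval 33.2 to 36.1), 20.4% and 18.7% in the DIV3 libraries, 13.6% ± 0.214 (SD, n = 2) at DIV5 and 6.81% ± 5.80 at DIV7, where the libraries stood at 10.9% and 2.71%. Ciliated (ependymal) cell-like cells were 2.10% of cells at DIV1, 2.55% ± 1.00 at DIV3, 8.58% ± 5.32 at DIV5 and 19.8% ± 8.74 at DIV7. Microglia or macrophage-like cells were 1.82%, 2.28% ± 1.03, 3.60% ± 2.78 and 6.29% ± 2.91 on the same days. Intermediate progenitor or neuroblast-like cells were 17.5% of the DIV1 library and 0.735% ± 0.313 at DIV3. GABAergic neuron-like cells were 4.49% at DIV1 and 0.772% ± 0.310, 1.79% ± 0.148 and 1.15% ± 0.622 afterwards. Radial glia or astrocyte-like cells differed most between replicates in percentage points. They made up 33.3% and 7.90% of cells in the DIV3 libraries and 9.69% and 46.5% in the DIV7 libraries. With the unnamed cluster described next added, they were 1721 of 5068 and 922 of 2824 cells at DIV3. At DIV7 they were then 1016 of 2953 and 2011 of 3511. An unnamed cluster led by Wisp2 and C1ql3, kept out of that class by a naming rule set after the clusters were seen, held 0.148% of cells at DIV1, 0.612% and 24.8% at DIV3, 23.7% and 7.33% at DIV5, and 24.7% and 10.7% at DIV7.

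Of the 13 classes, counting unnamed cells as 1, glutamatergic neuron-like cells alone followed the day by Pearson's r (r = -0.939, 7 libraries, exact two-sided permutation p = 0.0016, Benjamini-Hochberg adjusted p = 0.0206). Spearman's rho was -0.973 (exact permutation p = 0.0032, adjusted p = 0.0413), and without the 2 libraries farthest from the median day r lay between -0.977 and -0.865. For ciliated cell-like cells r was 0.822 (exact permutation p = 0.0127, adjusted p = 0.0825) and rho 0.918 (adjusted p = 0.0413), and r without the farthest 2 libraries was 0.805 to 0.913. Without any 1 of the 7 libraries the adjusted p for glutamatergic neuron-like cells rose to between 0.0722 and 0.144, with r from -0.977 to -0.906. The call ended with a stricter cell filter (r = -0.168) and with finer clustering (r = -0.125). Under these settings the DIV1 library kept 23 and 78 glutamatergic neuron-like cells in place of 1405, while all of its neuron-like clusters, unnamed ones included, held 2032 and 1614 cells. At DIV7 all neuron-like clusters held 58 and 73 cells with the stricter filter and 368 and 118 with finer clustering. Libraries of 2 days cannot be told apart by such a test, since 2 against 2 allows no p under 0.333.

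**Figure D1:**
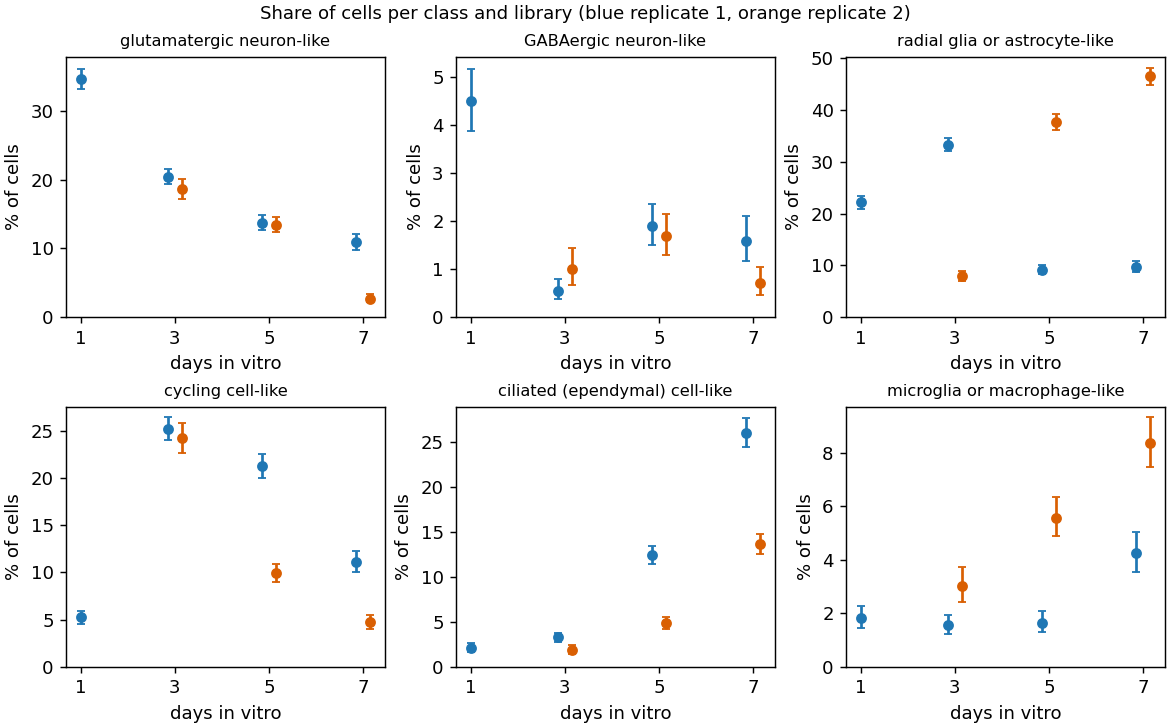
Share of cells (%, linear axes from 0) of 6 classes against days in vitro, 1 point per library with its exact binomial 95% interval. Glutamatergic neuron-like cells stood at 34.6% in the DIV1 library and at 10.9% and 2.71% in the DIV7 libraries.

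The main comparison asked how glutamatergic neuron-like cells differed between DIV3 and DIV7. Slc17a7 (ENSMUSG00000070570), the vesicular glutamate transporter VGLUT1, rose by 3.73 ± 0.54 (log2 ± SE, n = 2 libraries per day), from 15.4 ± 11.3 CPM (counts relative to the library's scaled total, mean ± SD) to 200.1 ± 25.3. Camk2a (ENSMUSG00000024617), a kinase of the postsynaptic density, rose by 3.00 ± 0.33, from 22.8 ± 11.3 to 180.2 ± 15.7 CPM. Slc12a5 (ENSMUSG00000017740), the chloride exporter KCC2, rose by 3.21 ± 0.37, and its counterpart, the chloride importer Slc12a2, changed by 0.60 ± 0.31 without passing the test. Grp (ENSMUSG00000024517), the gastrin-releasing peptide, fell from 88.1 ± 21.2 to 16.0 ± 1.73 CPM (log2 -2.44 ± 0.27), and Ddah2 (ENSMUSG00000007039) from 484.9 ± 118.5 to 114.5 ± 20.9 CPM (log2 -2.09 ± 0.24). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0155 for Slc17a7, 0.00157 for Camk2a, 0.00167 for Slc12a5, and 0.00143 for both Grp and Ddah2. In all, 989 of 13339 genes passed an adjusted p of 0.05, 645 higher and 344 lower at DIV7, and DESeq2 called 1184. Of the 989 edgeR calls 185 are genes at least 4 times higher in a non-neuronal class over all days pooled, with unnamed and cycling cells not compared.

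Among the largest rises by the rule fixed beforehand were Fxyd7, a regulator of the sodium pump, by 4.27 ± 0.39, Slc17a7, the noncoding Snhg11 by 3.67 ± 0.33, the lipoprotein lipase Lpl by 3.29 ± 0.44, Slc12a5, Camk2a, the synapse organiser C1ql3 by 2.92 ± 0.47, the chemokine Cx3cl1 by 2.91 ± 0.34 and Stum by 2.77 ± 0.28. The largest falls, besides Grp and Ddah2, were Sln (-2.70 ± 0.54), Fam181b (-2.32 ± 0.36), Cdk2ap1 (-2.27 ± 0.34), Ifitm2 (-2.23 ± 0.28), Fhl2 (-1.89 ± 0.38), Zeb1 (-1.84 ± 0.32), Ndfip1 (-1.82 ± 0.32) and Cdkn1c (-1.81 ± 0.39). Over all days pooled, Lpl, Fxyd7, Cx3cl1, Ifitm2 and Cdkn1c were over 4 times higher in another class than in these neurons. Lpl stood at 469.4 CPM in microglia-like cells and 100.7 in glutamatergic ones. C1ql3 leads, with Wisp2, an unnamed cluster that was not among the classes compared. At DIV7 itself Lpl stood in the glutamatergic sums at 123% and 53.6% of its microglial level, and its call was lost without DIV3 replicate 1 and without either DIV7 library. Of the other textbook genes chosen beforehand, the vesicle proteins Syn1 and Syp rose by 0.82 ± 0.20 (adjusted p = 0.0350) and 1.35 ± 0.31 (adjusted p = 0.0301), and Dlg4, which encodes the scaffold PSD-95, rose by 1.16 ± 0.31 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0484). Slc17a6 (-0.28 ± 0.31), Gap43 (0.20 ± 0.20), Dcx (0.09 ± 0.26), Grin2a (0.69 ± 0.42) and Grin2b (0.74 ± 0.25) did not pass. Without DIV7 replicate 1 and without DIV7 replicate 2 the adjusted p was 0.0693 and 0.0824 for Slc17a7, 0.149 and 0.186 for Syp, 0.161 and 0.230 for Syn1, and 0.287 and 0.107 for Dlg4. Without DIV3 replicate 1 it was 0.106 for Syn1 and 0.229 for Dlg4, and with only the libraries of both days it was 0.0540 for Syn1. For Dlg4 it was 0.0520 with total-count scaling, 0.0561 with top doublet scores removed, 0.0601 with all neuron-like clusters summed, 0.0502 with pyramidal-like clusters alone and 0.0855 in the dentate-like cluster alone. Of the genes named for this comparison 60 lost their call without DIV7 replicate 1, 60 without DIV7 replicate 2, 29 without DIV3 replicate 1 and 91 with a stricter cell filter. In the dentate-like cluster alone Syn1 was at 0.47 (edgeR adjusted p = 0.317) and Syp at 0.66 (adjusted p = 0.392), and 46 of the genes named lost their call there and 4 reversed. Without DIV3 replicate 2 Grin2a (edgeR adjusted p = 0.00112) and Grin2b (adjusted p = 0.00424) passed, and Grin2b also passed without a low-count filter (adjusted p = 0.0156).

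**Figure D2:**
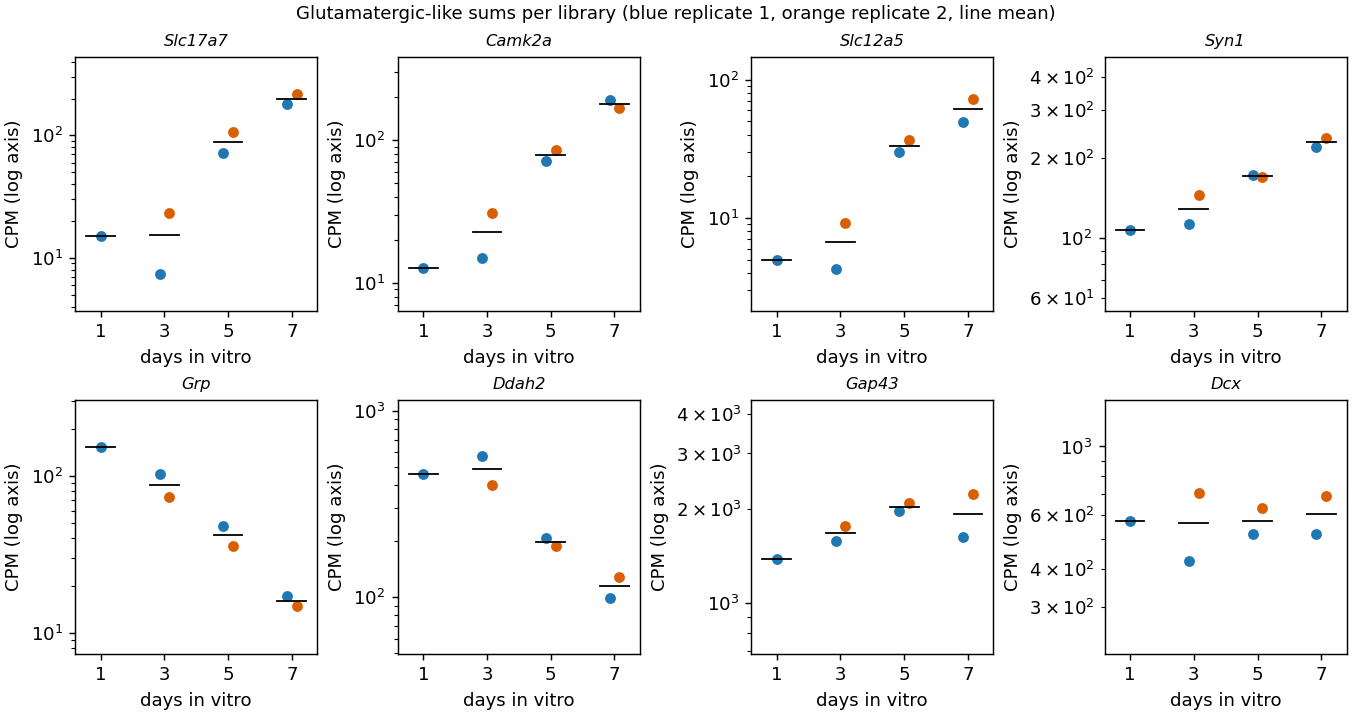
CPM (log axes) of 8 genes in sums over glutamatergic neuron-like cells against days in vitro, 1 point per library, with a line at the mean of each day. Slc17a7 stood at 15.4 CPM on average at DIV3 and 200.1 at DIV7, and Grp at 88.1 and 16.0.

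Many genes of the synapse rose. Of 51 genes of the presynaptic vesicle and release machinery 25 rose and 0 fell, among them Rimbp2 (3.56 ± 0.31), Rph3a (3.72 ± 0.34) and Nsf (1.72 ± 0.20), and adjusted over the list alone 28 rose and 2 fell. Of 42 postsynaptic scaffold and signalling genes 22 rose and 0 fell, with Nrgn up by 2.74 ± 0.23 and Ppp3ca by 1.42 ± 0.20, and 32 rose adjusted over the list alone. Voltage-gated ion channels rose in 18 of 49 genes, with Scn8a at 1.84 ± 0.22 and Kcnip2 at 2.48 ± 0.42, and none fell (adjusted over the list alone 23 rose and 0 fell). Synaptic adhesion genes rose in 20 and fell in 2 of 73 (30 and 2 adjusted over the list alone), with Nptxr at 2.03 ± 0.25 and Ntng1 at 3.36 ± 0.48. Glutamate receptor genes rose in 7 and fell in 1 of 39 (8 and 1 adjusted over the list alone), with Grm5 at 1.67 ± 0.23 and Gria3 at 1.85 ± 0.32, and genes of GABA and glycine receptors and the inhibitory postsynapse rose in 6 of 25 (10 adjusted over the list alone), with Gabra5 at 1.26 ± 0.25. Genes of CA1 or CA3 pyramidal identity rose in 9 and fell in 1 of 26 (10 and 3 adjusted over the list alone), with Crym at 1.19 ± 0.19; Crym was at -0.65 in the dentate-like cluster alone. Immediate early and activity-regulated genes had a median of 1.14 and were called up by camera with Benjamini-Hochberg adjustment (adjusted p = 3.34e-07; adjusted p = 0.579 with an estimated correlation), and 3 of 38 rose, Rasgrp1, Dusp5 (2.19 ± 0.33) and Plk2 (1.01 ± 0.26), and 3 rose and 1 fell adjusted over the list alone. Rasgrp1 had 3 counts at DIV3 and 64 at DIV7, a ratio of 70.6 (counting interval 23.1 to 352).

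Several lists were lower at DIV7 by camera with a preset correlation, and none of them with an estimated correlation. Cell cycle genes fell in 3 of 51, Cdk4 (-1.43 ± 0.24), Mcm7 (-1.46 ± 0.32) and Mcm6 (-1.42 ± 0.34), and in 3 adjusted over the list alone. Intermediate progenitor or neuroblast markers fell in 5 of 11, among them Igfbpl1 (-1.63 ± 0.26) and Insm1 (-1.75 ± 0.34), and in 6 adjusted over the list alone. Cholesterol biosynthesis genes fell in 3 of 26 (Fdps -1.44 ± 0.27, Fdft1 -0.87 ± 0.22, Acat2 -1.28 ± 0.32), and in 4 adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes fell in 3 of 74 (0 adjusted over the list alone) with a median of -0.21, and ribosomal protein genes in 3 of 80 (1 adjusted over the list alone) with a median of -0.35. In the dentate-like cluster alone the medians of the cholesterol and oxidative phosphorylation lists were 0.14 and 0.06. The interferon response list had a median of -1.63 over 25 genes, but -0.18 without DIV3 replicate 1. Its lower median rests on that library. The sums of its 31 genes stood at 753 CPM in DIV3 replicate 1 and 175 in DIV3 replicate 2, and at 190.5 and 137 in the DIV7 replicates. It had 0 members down and Irf1 up by 1.93 ± 0.42 (1 up adjusted over the list alone), a call lost without DIV3 replicate 1 and without either DIV7 library.

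Markers of other cells moved in the same sums. Microglia or macrophage markers had a median change of 2.71, and 4 of 21 rose (7 adjusted over the list alone): Lpl, Cx3cr1 (0.409 to 7.85 CPM), Ctss (0.271 to 4.39 CPM) and Trem2, which had 2 counts at DIV3 and 29 at DIV7, a ratio of 48.0 (counting interval 12.1 to 415). Ciliated cell markers had a median of 1.41 with 5 of 14 up (9 adjusted over the list alone), for example Meig1 by 2.50 ± 0.44. Astrocyte maturation genes rose in 8 of 35 (16 adjusted over the list alone), with Mt1 up by 2.52 ± 0.27 and Aqp4 by 2.61 ± 0.36, both over 4 times higher in another class. Reactive astrocyte genes rose in 3 and fell in 1 of 36 (8 and 3 adjusted over the list alone), and their median of 0.75 became -0.24 once genes far higher in another class were left out. Mural cell markers had a median of -0.80 with 1 of 12 down (1 adjusted over the list alone), and mitochondrially encoded genes had a median of 0.45 over 13 genes with 0 past the test (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0472; adjusted p = 0.667 with an estimated correlation). Of 31 radial glia or astrocyte markers 2 rose and 2 fell (8 and 3 adjusted over the list alone).

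By limma's camera with a preset correlation and Benjamini-Hochberg adjustment, 22 of 40 lists were called, 14 up and 8 down. The adjusted p was 6.08e-09 for the presynaptic, 3.10e-13 for the postsynaptic, 8.66e-09 for the ion channel, 2.74e-05 for the cell cycle and 4.41e-06 for the microglia list. No list was called by camera with an estimated correlation, where the smallest adjusted p was 0.473. The largest among the called lists was 0.675 with an estimated correlation. With 3 residual degrees of freedom behind the estimate, this lack of calls decides little about a list. The count of genes was 120 without DIV7 replicate 1, 123 without DIV7 replicate 2, 381 without DIV3 replicate 1 and 2977 without DIV3 replicate 2, and 1 with a stricter cell filter that left 40 glutamatergic cells in DIV7 replicate 1. Clusters 5 (dentate-like, led by Prox1) and 7 (Cck and Stmn2 among its top genes) held most of the class at DIV3, DIV5 and DIV7. The dentate-like cluster alone gave 472 genes. It held 601 of 1035 and 166 of 527 cells of the class in DIV3 replicates 1 and 2. At DIV5 it held 273 of 588 and 205 of 519, and at DIV7 171 of 322 and 34 of 95. Its part was thus larger in replicate 1 on each of these days, which the main fit does not model.

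**Figure D3:**
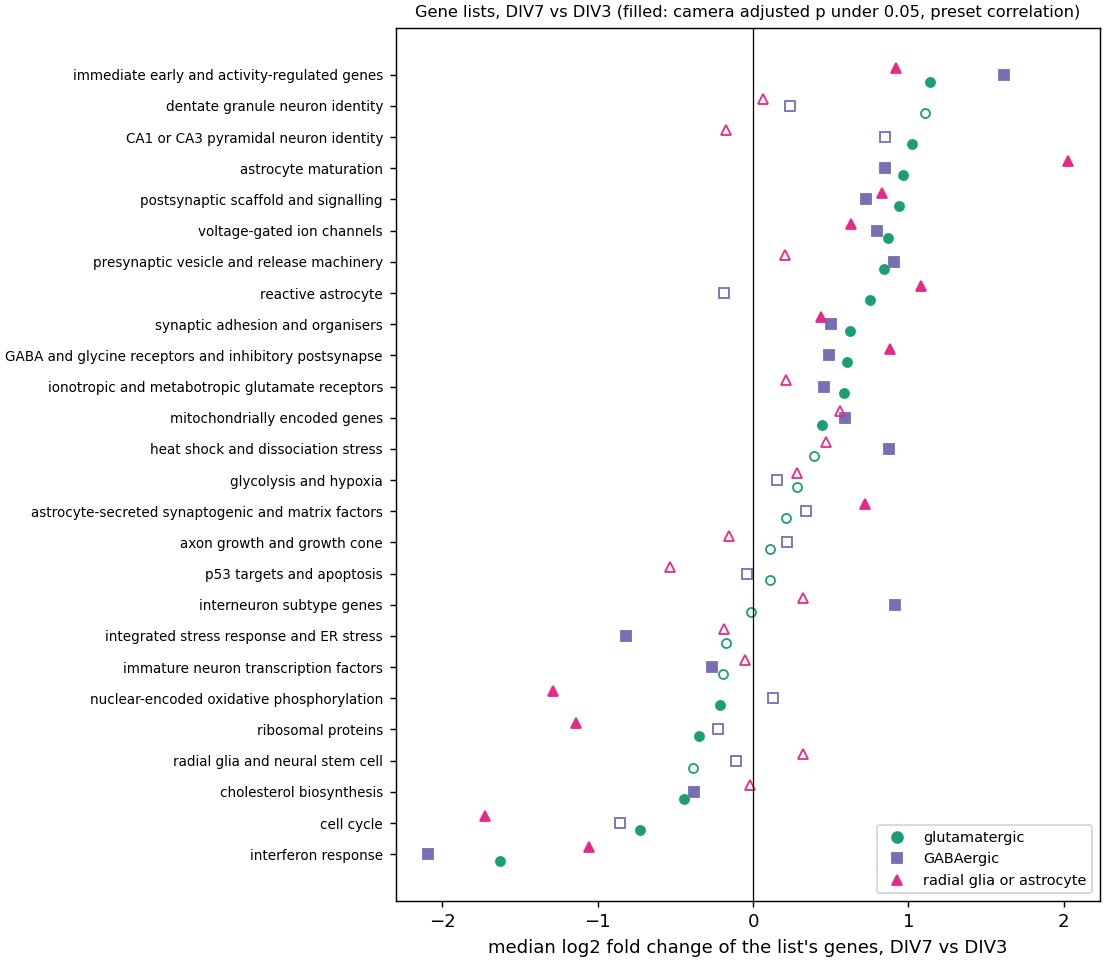
Median log2 fold change (DIV7 against DIV3) of the genes of 26 lists fixed beforehand, in 3 cell classes; filled symbols passed camera with a preset correlation, and no list passed in any of these classes with an estimated correlation. Presynaptic genes had medians of 0.85 in glutamatergic and 0.91 in GABAergic neuron-like cells, and ribosomal protein genes a median of -1.14 in radial glia or astrocyte-like cells.

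Between DIV3 and DIV5 a small set of genes differed in glutamatergic neuron-like cells. Rprml rose by 2.49 ± 0.37 (log2 ± SE, n = 2 libraries per day), Fxyd7 by 2.46 ± 0.38, Mal2 by 2.42 ± 0.38, Snhg11 by 2.40 ± 0.32 and Slc12a5 by 2.35 ± 0.36, while Ifitm2 (-1.82 ± 0.26), Pdlim4 (-1.39 ± 0.25), Ddah2 (-1.30 ± 0.23) and Id1 (-1.24 ± 0.22) fell. Presynaptic genes rose in 5 of 51, among them Rimbp2 (2.93 ± 0.30), and in 20 adjusted over the list alone; postsynaptic genes rose in 2 of 42, Nrgn (2.09 ± 0.23) and Camk2a (1.81 ± 0.31), and in 18 adjusted over the list alone. Microglia markers had a median of 1.37 and ciliated cell markers of 0.72, with 0 members past the test, and oligodendrocyte markers a median of 0.91 (-0.11 without DIV5 replicate 2). By edgeR with Benjamini-Hochberg adjustment 61 of 13339 genes passed, 54 higher and 7 lower, with an adjusted p of 0.0375 for Rprml and 0.0404 for Ddah2; DESeq2 called 224. With only the libraries of both days every gene named here lost its call, and without either DIV7 library every one but Rimbp2 and Nrgn did. Without DIV3 replicate 1, DIV5 replicate 2, DIV7 replicate 1 or DIV7 replicate 2 the adjusted p (edgeR, Benjamini-Hochberg) was 0.0784, 0.0895, 0.0845 and 0.0820 for Slc12a5 and 0.0701, 0.166, 0.127 and 0.128 for Camk2a. With only both days it was 0.140 for Slc12a5 and 0.167 for Camk2a. Camk2a stood at 0.192 with thinned sums, 0.0502 with doublets kept and 0.0579 with top doublet scores removed. Pdlim4 was at 1.09 in the dentate-like cluster alone. Camera called 18 of 40 lists, 0 with an estimated correlation (smallest adjusted p = 0.529 with an estimated correlation). The count was 7 without DIV7 replicate 1 and without DIV7 replicate 2, 8 without DIV3 replicate 1, 21 without DIV5 replicate 2 and 1385 without DIV3 replicate 2, and 0 with only the libraries of these days or with a stricter cell filter.

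From DIV5 to DIV7 no gene of the glutamatergic neuron-like sums passed the main fit. Slc17a7 changed by 1.16 ± 0.49 and Camk2a by 1.20 ± 0.30 (log2 ± SE, n = 2 libraries per day), and Syp by 0.61 ± 0.30. Of 13339 genes 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 675 had an unadjusted p under 0.05, and DESeq2 called 4. The 675 are close to the 0.05 share of genes that would lie under that limit with no change at all. Limma's camera with Benjamini-Hochberg adjustment called 15 of 40 lists: postsynaptic genes had a median of 0.34 (adjusted p = 2.73e-07) and cell cycle genes of -0.70 (adjusted p = 6.08e-09), while microglia markers had a median of 1.68 and ciliated markers of 0.72. No list held with an estimated correlation (smallest adjusted p = 0.453 with an estimated correlation). Adjusted over the list alone 0 postsynaptic genes and 3 cell cycle genes passed, the latter down.

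In glutamatergic neuron-like cells DIV3 was compared with the DIV1 library, which has no replicate and is assumed to vary like the other days. The p-values below hold only under that assumption, and a state of that library alone is not told apart from its day. Zfp771 rose by 3.43 ± 0.34 (log2 ± SE, n = 1 and 2 libraries), Habp4 by 2.75 ± 0.31, Nbl1 by 2.59 ± 0.30 and Cnih2, an auxiliary subunit of AMPA receptors, by 2.59 ± 0.37, while Snhg11 (-2.38 ± 0.36), Mthfd2 (-2.12 ± 0.30), Msi2 (-2.03 ± 0.34) and Insm1 (-1.82 ± 0.31) fell. Aqp4 rose by 4.08 ± 0.62 to 9.71 CPM, beside 1033 CPM in radial glia or astrocyte-like cells over all days pooled. The collagen genes Col1a1 (4.43 ± 0.49) and Col1a2 (4.61 ± 0.57) of fibroblasts rose too. Fibroblast or meningeal cell-like cells were 0.123% of the DIV1 library and 10.4% ± 2.97 at DIV3. GABAergic neuron markers had a median of -2.60 in these sums, with 0 of 15 past the test and 9 down adjusted over the list alone. By edgeR with Benjamini-Hochberg adjustment 38 of 13339 genes passed, 25 higher and 13 lower, with an adjusted p of 0.00903 for Zfp771 and 0.0293 for Snhg11; DESeq2 called 163. Camera called 14 of 40 lists, 0 with an estimated correlation (smallest adjusted p = 0.369 with an estimated correlation). Cluster 10, led by Grp and Neurod6, held most glutamatergic cells of DIV1 and few of any other day. The count was 9 without DIV7 replicate 2, 15 without DIV7 replicate 1, 62 without DIV5 replicate 2, 68 without DIV5 replicate 1 and 677 without DIV3 replicate 2, 7 with finer clustering, where Snhg11 was at 0.31, and 0 with a stricter cell filter.

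GABAergic neuron-like cells, defined by Sst, Npy, Gad1 and Gad2, showed higher activity-regulated genes at DIV7 than at DIV3. Phlda1 rose by 4.87 ± 0.49 (log2 ± SE, n = 2 libraries per day), from 9.10 ± 3.02 to 265.8 ± 96.2 CPM, and the transcription factor Egr4 by 3.72 ± 0.82, a call lost without the DIV1 library, without either DIV3 library, without DIV7 replicate 1 and with several other settings, total-count scaling and finer clustering among them. Egr2, Cx3cl1 and Socs3 each had 3 counts at DIV3 and 88, 86 and 68 at DIV7, ratios of 18.2 (counting interval 6.04 to 90.1), 17.8 (5.90 to 88.1) and 14.1 (4.62 to 70.0). Immediate early and activity-regulated genes rose in 18 and fell in 0 of 36, with Junb up by 2.89 ± 0.30, Jun by 2.22 ± 0.26, Nr4a2 by 2.63 ± 0.38 and Npas4 by 2.14 ± 0.32, and 23 rose adjusted over the list alone. Presynaptic genes rose in 10 of 44 (24 adjusted over the list alone), with Sncb up by 2.25 ± 0.31 and Cplx1 by 1.80 ± 0.32, and Slc12a5 rose by 2.01 ± 0.49. Without DIV3 replicate 1 and without DIV7 replicate 1 the adjusted p (edgeR, Benjamini-Hochberg) of Slc12a5 was 0.280 and 0.0891. It was 0.104 with DESeq2, and with edgeR 0.0721 with thinned sums, 0.0630 with doublets kept, 0.0601 with top doublet scores removed, and 0.0562 both with finer clustering and with a graph without its weakest edges. Egr2, Socs3 and Npy lost their calls without DIV3 replicate 1. GABAergic neuron markers rose in 4 of 18 (6 adjusted over the list alone), Npy by 1.64 ± 0.29 and Gad2 by 1.15 ± 0.28. Heat shock and dissociation stress genes, a list that shares Junb, Jun and Socs3 with those above, rose in 7 of 17 (8 rose and 1 fell adjusted over the list alone). Mitochondrially encoded genes were called up as well, with a median of 0.59 and 0 of 13 past the test (3 up adjusted over the list alone; camera with Benjamini-Hochberg adjustment, adjusted p = 0.0107; adjusted p = 0.512 with an estimated correlation). Astrocyte maturation genes rose in 4 and fell in 1 of 22 (5 and 1 adjusted over the list alone; adjusted p = 0.000928 by camera; adjusted p = 0.509 with an estimated correlation).

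Transcription factors of glutamatergic neurons fell in the same sums. Neurod1 and Neurod2 had 51 and 30 counts at DIV3 and 0 at DIV7, at least 27.3-fold and 16.1-fold lower against a floor of 3 counts over the day. Bhlhe22 had 28 counts at DIV3 and 1 at DIV7, a ratio of 45 (counting interval 7.45 to 1840), and Neurod6 34 and 2, a ratio of 27.3 (7.01 to 235). These intervals take UMIs as independent, while the counts lay in few cells. Of the 28 GABAergic neuron-like cells of each DIV3 library, 27 and 23 held fewer than 3 UMIs of these 4 genes. Over 18 genes higher in glutamatergic cells, the top 11 of 56 DIV3 cells held 86.3% of 1071 UMIs. Igfbpl1, expressed in neuroblasts, fell by 3.69 ± 0.58. Glutamatergic neuron markers fell in 5 of 12 (6 adjusted over the list alone). The astrocyte gene Gfap rose by 2.78 ± 0.57 to 217.1 CPM, beside 7653 CPM in radial glia or astrocyte-like cells over all days pooled. By edgeR with Benjamini-Hochberg adjustment 260 of 8372 genes passed, 190 higher and 70 lower, with an adjusted p of 2.26e-06 for Phlda1, 0.0494 for Egr4, 0.00228 for Egr2 and 0.0167 for Neurod1; DESeq2 called 129. Scaling by total count alone, which shifted the median gene by -0.12, moved the share of higher genes from 73.1% to 56.3%. Camera called 18 of 34 lists, the activity-regulated one with an adjusted p of 1.50e-11 (adjusted p = 0.512 with an estimated correlation), and 0 with an estimated correlation. The sums rest on 25 to 47 cells per DIV3 or DIV7 library; the count was 53 without DIV3 replicate 1, 145 without DIV7 replicate 2, 160 without DIV7 replicate 1, 420 without DIV5 replicate 2 and 424 without DIV5 replicate 1, and 392 once cells with at least 3 UMIs of Neurod1, Neurod2, Neurod6 and Bhlhe22 were left out.

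Sums over radial glia or astrocyte-like cells had higher astrocyte genes and lower cell cycle, ribosomal and respiratory chain genes at DIV7 than at DIV3. The libraries drew on different clusters, as given below, so a change within cells is not told apart from a difference in the cells summed. Fam107a (ENSMUSG00000021750) rose by 5.93 ± 0.60 (log2 ± SE, n = 2 libraries per day), from 1.96 ± 2.07 to 168.7 ± 47.9 CPM. Slc22a4 rose by 4.99 ± 0.34, the retinal dehydrogenase Aldh1a1 by 4.81 ± 0.36, and Ccdc3 by 4.10 ± 0.43. Tesc (-5.04 ± 1.01), Pcp4 (-3.84 ± 0.61), Bex1 (-3.15 ± 0.25), the replication factor Pclaf (-3.15 ± 0.51) and Ncald (-2.91 ± 0.50) fell. GABAergic neuron-like cells held Bex1 at 393.5 CPM over all days pooled. Markers of glutamatergic neurons were present in the glial sums and lower at DIV7. There 8 abundant markers stood at a median of 19.8% and 17.6% of their glutamatergic level in the DIV3 libraries and 7.73% and 3.92% in the DIV7 libraries. The markers did not share a single fraction. Over all days pooled Fezf2 was at 77.2 CPM in glia beside 103.8 in glutamatergic cells. The less abundant marker Slc17a7, at 54.65 CPM in glutamatergic cells, was at no more than 0.956 in any other class compared. The median of the 8 is therefore no measure of neuronal RNA in glia. The full marker list was not called, with 1 of 12 up and 3 down (2 and 3 adjusted over the list alone). Whether RNA of neurons accounts for falls of genes that neurons hold, such as Bex1 and Pcp4, was not tested. Pcp4 stood at 427.2 CPM in glutamatergic neuron-like cells over all days pooled. Astrocyte maturation genes rose in 28 and fell in 0 of 38 (31 rose adjusted over the list alone), with Gja1, the gap junction protein connexin 43, up by 3.44 ± 0.34 and Mlc1 by 2.30 ± 0.25. Reactive astrocyte genes rose in 17 and fell in 2 of 40 (19 and 2 adjusted over the list alone), with Gfap up by 2.56 ± 0.31 and Serpina3n by 2.16 ± 0.24. Cell cycle genes fell in 27 of 50 (34 adjusted over the list alone), with Mcm2 at -2.45 ± 0.41 and Cdk4 at -1.71 ± 0.30. Ribosomal protein genes fell in 65 of 80 (69 adjusted over the list alone), with Rpl8 at -1.61 ± 0.20, and nuclear-encoded oxidative phosphorylation genes in 57 of 74 (62 adjusted over the list alone), with Ndufv2 at -1.77 ± 0.27. Of the p53 and apoptosis list, which was not called, 6 of 25 fell and 0 rose (6 and 0 adjusted over the list alone). Among them were Bax (-1.51 ± 0.29) and Cdkn1a (-1.90 ± 0.45). With a stricter cell filter Bax was at 0.27 and Cdkn1a at 0.83, and Cdkn1a was at 0.42 with a looser filter and 0.67 with finer clustering. Ciliated cell markers rose in 7 of 18 (14 adjusted over the list alone) with a median of 1.92, and microglia markers in 1 of 22 (0 adjusted over the list alone) with a median of 1.68.

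By edgeR with Benjamini-Hochberg adjustment 3070 of 13848 genes passed, 1502 higher and 1568 lower at DIV7, with an adjusted p of 0.00430 for Fam107a, 0.00387 for Aldh1a1 and 0.00397 for Bex1; DESeq2 called 2951. Camera called 16 of 41 lists, ribosomal proteins with an adjusted p of 2.20e-21 and astrocyte maturation with 4.63e-11, and 0 with an estimated correlation (adjusted p = 0.552 and 0.631 with an estimated correlation). Different clusters held the class. Cluster 6, led by Lcn2, Ifit3 and Isg15, held 1528 of the 1690 cells of DIV3 replicate 1. Cluster 2, led by Slc1a2 and Scd1, held 1326 of the 1634 cells of DIV7 replicate 2. The score over the radial glia or astrocyte markers was 0.296 for cluster 6, with 0 of them among its top genes. It was 0.74 for cluster 2, with 4 among its top genes, and 0.406 for the unnamed cluster 1. The naming rule thus bears on the higher astrocyte genes. The count was 155 without DIV7 replicate 2, 713 without DIV3 replicate 1 and 899 without DIV7 replicate 1, and it was 471 with coarser clustering, 704 with a stricter cell filter and 0 with finer clustering.

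**Figure D4:**
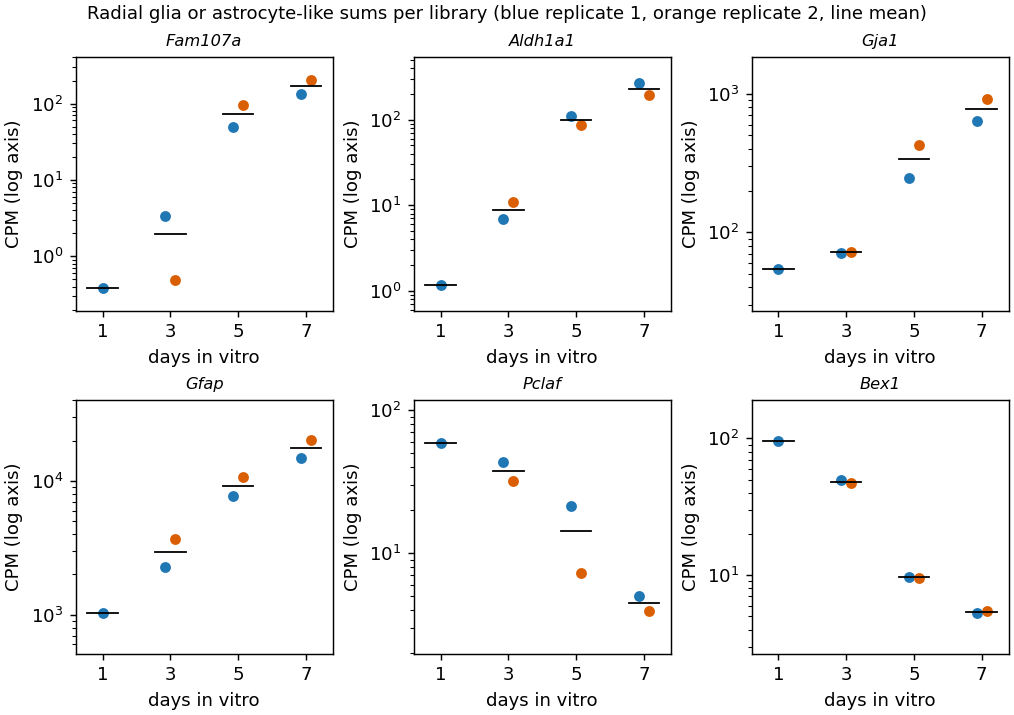
CPM (log axes) of 6 genes in sums over radial glia or astrocyte-like cells against days in vitro, 1 point per library, with a line at the mean of each day. Fam107a stood at 1.96 CPM on average at DIV3 and 168.7 at DIV7, and Bex1 at 48.3 and 5.42.

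Whether the classes changed differently was tested with the library as a block. Against GABAergic neuron-like cells, the change from DIV3 to DIV7 in glutamatergic cells was more positive for Bhlhe22 by 5.79 ± 0.75, Neurod6 by 4.77 ± 0.72, Lmo1 by 4.33 ± 0.80 and Fezf2 by 4.08 ± 1.00 (log2 ± SE, n = 2 libraries per day), and more negative for Sln (-3.15 ± 0.76), Nanos1 (-2.73 ± 0.44), Dusp14 (-2.66 ± 0.65), Sesn3 (-2.66 ± 0.41) and Cryab (-2.63 ± 0.37). Neurod2, at 0 counts in the DIV7 GABAergic sums, passed too. A more positive difference need not be a rise in glutamatergic cells. In their sums the mean at DIV3 and DIV7 was 428 and 375 CPM for Neurod2 and 87.7 and 78.1 for Fezf2. It was 379 and 421.6 CPM for Neurod6, 344.2 and 476.9 for Bhlhe22, and 93.5 and 172.6 for Lmo1. By edgeR with Benjamini-Hochberg adjustment 192 of 11190 genes passed, 45 more positive and 147 more negative, with an adjusted p of 1.67e-07 for Bhlhe22 and 0.0117 for Fezf2; DESeq2 called 47. With total-count scaling, which shifted the median gene by 0.15, the share of more positive genes moved from 23.4% to 46.1%. Without GABAergic cells holding glutamatergic transcripts, which by construction hold most Neurod6 counts, Neurod6 was at -6.07 and Fezf2 at -5.36. Neither passed (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.7005 and 0.804). The count was 78 without DIV3 replicate 1 and without DIV7 replicate 1, 87 without DIV3 replicate 2 and 127 without the DIV1 library.

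Against radial glia or astrocyte-like cells, the change was more positive in glutamatergic cells for genes such as Hs6st2 by 4.03 ± 0.59, the calmodulin-binding Pcp4 by 3.91 ± 0.43, Stum by 3.90 ± 0.65 and Cx3cl1 by 3.83 ± 0.75 (log2 ± SE, n = 2 libraries per day). It was more negative for the matrix protein Tnr (-3.78 ± 0.43), Cdc42ep4 (-3.20 ± 0.43), Nkain4 (-3.09 ± 0.49), Tagln3 (-3.06 ± 0.51) and the astrocyte glutamate transporter Slc1a2 (-3.02 ± 0.41). The fall of glutamatergic markers in the glial sums may add to the more positive differences, which was not tested. By edgeR with Benjamini-Hochberg adjustment 788 of 14614 genes passed, 364 more positive and 424 more negative, with an adjusted p of 0.00157 for Tnr; DESeq2 called 812. The count was 102 without DIV7 replicate 2 and 160 without DIV7 replicate 1, and 9 with finer clustering.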

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

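The tests of the difference between classes were planned; of the weighings, those of microglial RNA, of Lpl, of synaptic genes, of glutamatergic RNA in GABAergic cells and of DIV3 replicate 1 alone were chosen after the result was seen.

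The change from DIV3 to DIV7 differed between classes by a test of the difference itself (edgeR, library as a block). Against GABAergic neuron-like cells 192 genes differed. The largest log2 differences were 10.49 for Neurod2, 5.79 for Bhlhe22, 4.77 for Neurod6, 4.33 for Lmo1 and 4.08 for Fezf2. Neurod2 had 0 counts in the DIV7 GABAergic sums, so its fitted value is no bound. In the glutamatergic sums the mean of Neurod2 and Fezf2 was lower at DIV7 than at DIV3, while that of Bhlhe22, Neurod6 and Lmo1 was higher. Without GABAergic cells holding glutamatergic transcripts Neurod6 was at -6.07 and Fezf2 at -5.36, neither past the test. The most negative were -3.15 for Sln, -2.73 for Nanos1, -2.66 for Dusp14, -2.66 for Sesn3 and -2.63 for Cryab. Against radial glia or astrocyte-like cells 788 genes differed, among them Hs6st2 at 4.03, Pcp4 at 3.91, Stum at 3.90 and Cx3cl1 at 3.83, and Tnr at -3.78, Cdc42ep4 at -3.20, Nkain4 at -3.09, Tagln3 at -3.06 and Slc1a2 at -3.02.

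Some markers of other cells rose in the glutamatergic sums. RNA of the non-neuronal classes compared is argued against as the source of most of the raised synaptic genes. Over 74 raised members the highest such class stood at a median of 0.178 times the DIV7 glutamatergic level. Of them 11 members were higher in such a class. The members were chosen as raised in these same sums, which favours a low ratio, and unnamed and cycling cells were not compared. Lpl stood at no less than 53.6% of its microglial level, far above the 0.132% and 0.565% at which the median microglial marker stood in the DIV7 libraries, so microglial RNA does not account for it. For the microglial and ciliated markers themselves RNA from those cells cannot be told apart from other sources, since 59.1% and 62.5% of abundant markers lay within 3 times their median fraction, between the bounds set. The day stays open as a biological difference, and a change in other cells' share goes with the day.

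Glutamatergic transcription factors fell in the GABAergic sums. Glutamatergic RNA or whole glutamatergic cells among the GABAergic ones at DIV3 is a candidate explanation, since 94.4% of 18 genes, chosen as at least 10 times higher in glutamatergic than in GABAergic sums of DIV5 and DIV7, lay within 3 times their median fraction (22.2%) of the glutamatergic level at DIV3. A few cells holding both programmes is another, since the top 11 of 56 cells held 86.3% of 1071 UMIs, while 47 cells held at least 1. RNA in droplets, spread evenly over cells, would not place 86.3% of the UMIs in the top 20% of cells. For these 18 genes this argues against it as the source of most of the UMIs. The depth of each cell was not weighed, and droplet RNA stays open for the smaller part. Whole glutamatergic cells, doublets and maturing cells remain open.

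The interferon response list had a lower median at DIV7, with 0 members lower past the edgeR test. The state of DIV3 replicate 1 alone may account for the lower median in radial glia or astrocyte-like cells, where the median was 0.18 without that library. Glial RNA is a candidate source in the glutamatergic sum of that library, where 8 interferon genes stood at 9.17% of the glial level and 19 astrocyte markers at 3.99%, a ratio of 2.30. Replicate 1 also stood above replicate 2 in glia at DIV5 and DIV7, so a difference between the replicate numbers on every day stays open. A response of the neurons themselves in that library was not tested.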

How the results depend on the processing

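Removal of top doublet scores, the graph without its weakest edges, the pyramidal-like, dentate-like and wider glia classes, and leaving out genes far higher elsewhere or GABAergic cells with glutamatergic transcripts were chosen after seeing the data; the other alternatives were planned. Where a value below moved, the cause was not tested, apart from fewer genes, libraries or cells entering by construction. Over named genes, alternatives other than leaving out a library kept direction and side of the threshold in 4531 comparisons, lost the call in 821, gained it in 2 and reversed in 20; over called gene lists they kept 1493, lost 194 and reversed 19, and camera with an estimated correlation, counted apart, lost all 103. Leaving out a library kept 1601 named-gene results, lost the call in 596, gained it in 2 and reversed 4, and kept 620 lists, lost 81 and reversed 5. With RLE size factors 317 named-gene results kept their call and 1 lost it, and with total-count scaling 306 and 12.

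The counts below are genes past the threshold in glutamatergic neuron-like cells for DIV7 against DIV3 (989), DIV5 against DIV3 (61), DIV7 against DIV5 (0 by edgeR, 675 unadjusted) and DIV3 against DIV1 (38), in GABAergic neuron-like cells (260) and radial glia or astrocyte-like cells (3070) for DIV7 against DIV3, and for the glutamatergic minus GABAergic (192) and minus glial (788) change. DESeq2 gave 224 for DIV5 against DIV3, 4 for DIV7 against DIV5, 163 for DIV3 against DIV1, 129 for GABAergic cells and 47 for the GABAergic difference. Without a low-count filter the counts were 2264, 688, 65 and 546 in glutamatergic cells, 453 in GABAergic cells and 1433 for the glial difference; with a mean of at least 20 CPM they were 652 (DIV7 against DIV3), 36 (DIV5 against DIV3), 17 (DIV3 against DIV1) and 75 (GABAergic difference), and 14 gene lists in place of 22 were called. With only the libraries of both days 0 genes passed for DIV5 against DIV3 and 192 for DIV3 against DIV1. Thinned sums gave 32 and 18 for these comparisons, and doublets kept gave 59 for the latter. With all neuron-like clusters summed 110 genes passed for DIV5 against DIV3, and with pyramidal-like clusters alone 148. With an estimated correlation camera called 0 gene lists.

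The replicate number as a block gave 2963, 795, 19 and 1150 genes in glutamatergic cells, 595 in GABAergic and 4732 in radial glia or astrocyte-like cells. Replicate differences correlated across genes between days by 0.502, 0.301 and 0.488 in glutamatergic, 0.219, 0.124 and 0.283 in GABAergic, and 0.369, 0.357 and 0.739 in radial glia or astrocyte-like cells. Each comparison has only 2 same-numbered pairs and the labels name no shared culture, so the block is not taken as a pairing, although every one of these correlations is positive. Under the block Grin2b passed for DIV7 against DIV3 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0265), which it did not without.

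The stricter cell filter gave 1, 0 and 0 genes for DIV7 against DIV3, DIV5 against DIV3 and DIV3 against DIV1 in glutamatergic cells, 704 in radial glia or astrocyte-like cells, 140 for the glial difference and 0 classes following the day (glutamatergic share r = -0.168, unnamed share -0.845). Under it, DIV3 against DIV1, cycling markers were at -1.16, cell cycle at -0.68, CA1 or CA3 identity at 0.93, adhesion at 0.42, Snhg11 at 8.21, Insm1 at 0.16 and Rasgrp1 at 2.18; Gap43 was at -0.29 for DIV7 against DIV3, and in glia Gdf15 was at 0.60, Bax at 0.27, Aen at 0.083 and Cdkn1a at 0.83. GABAergic results were not run under it, with 17 and 13 cells at DIV7. The looser filter gave 1277 for the glial difference, Cdkn1a at 0.42 and an unnamed share of -0.679. The wider glia class gave Cdkn1a at 0.62, and doublets kept gave an unnamed share of -0.0611.

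Leiden resolution 0.5 gave 471 genes in glia, 167 for the glial difference, and r of 0.0412 for cycling and -0.0737 for glial shares. Resolution 2 gave 7 genes for DIV3 against DIV1, 0 in glia by edgeR, 114 and 9 for the GABAergic and glial differences, 0 classes following the day (glutamatergic r = -0.125, unnamed -0.783) and Cdkn1a at 0.67. Under it, DIV3 against DIV1, radial glia markers were at -0.068, cycling markers at 0.092 (the test reversed), CA1 or CA3 identity at 0.23, cell cycle at -0.090, Snhg11 at 0.31 and Rasgrp1 at 3.01.

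The dentate-like cluster alone gave 472 genes for DIV7 against DIV3 and 124 for DIV3 against DIV1. There cholesterol biosynthesis was at 0.14, oxidative phosphorylation at 0.063 (0.11 for DIV7 against DIV5), Cdkn1c at 0.23, Slc17a6 at 0.24, Crym at -0.65 and Vim at 0.40. Fibroblast markers were at 0.76 and Pdlim4 at 1.09 for DIV5 against DIV3, oligodendrocyte markers at 0.11 for DIV7 against DIV5 and immature transcription factors at -0.14 (the test reversed) for DIV3 against DIV1. Leaving out genes far higher elsewhere gave 21 for DIV3 against DIV1, 122 for the GABAergic difference, and reactive astrocyte medians of -0.24 and -0.34 for DIV7 against DIV3 and against DIV5; a mean of at least 20 CPM gave -0.24 and -0.45. Without GABAergic cells holding glutamatergic transcripts 392 GABAergic genes passed, immature transcription factors were at 0.074, and the differences of Neurod6 and Fezf2 were at -6.07 and -5.36, neither past the test.

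Leaving out 1 library, assuming a lone library to vary like the others, gave 120 to 2977 genes for DIV7 against DIV3, 7 to 1385 for DIV5 against DIV3, 0 to 1 for DIV7 against DIV5 and 9 to 677 for DIV3 against DIV1. It gave 53 to 424 in GABAergic cells, 155 to 3033 in glia, 78 to 244 and 102 to 1094 for the GABAergic and glial differences, 19 to 22 gene lists and 0 classes following the day, with glutamatergic r from -0.977 to -0.906. For DIV5 against DIV3 radial glia markers ran from -0.0019 (without DIV5 replicate 2) to 0.98 and oligodendrocyte markers from -0.11 (without the same library) to 1.46, and mural markers for DIV7 against DIV5 from -1.52 to 0.058 (without DIV7 replicate 2). For DIV7 against DIV3 the interferon list ran from -6.96 to 0.89 in GABAergic cells and from -1.58 to 0.18 in glia, both highest without DIV3 replicate 1. Slc17a6 ran from -0.63 to 0.16 (without DIV3 replicate 2), Gap43 from -0.032 (without DIV7 replicate 2) to 0.42, and Dcx from -0.23 (without DIV3 replicate 1; -0.12 without DIV7 replicate 2) to 0.52. Shares had r from -0.623 to 0.689 for Cajal-Retzius and -0.733 to 0.304 for GABAergic cells, both highest without DIV1, from -0.718 (without DIV1) to 0.607 for fibroblasts and from -0.232 (without DIV7 replicate 2) to 0.476 for glia.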

Other observations

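The interferon and glial immune genes were seen to differ between replicates before these values were drawn up, and no test was planned for them. In radial glia or astrocyte-like cells Lcn2 stood at 663 CPM in DIV3 replicate 1 and 2.03 in replicate 2, at 552 and 9.99 in the DIV5 replicates, and at 377 and 36.9 in the DIV7 replicates. Isg15 stood at 467 and 60.9 in the DIV3 replicates and at 41.1 and 13.9 at DIV7. Other genes ran the other way on some days: Ifit3 stood at 11.0 CPM in replicate 1 and 20.5 in replicate 2 at DIV7, and Cxcl1 at 36.7 and 48.2 at DIV5 and 14.2 and 17.1 at DIV7. The 31 genes of the interferon list summed in these cells to 6595 CPM in replicate 1 and 1577 in replicate 2 at DIV3, 3514 and 1166 at DIV5, and 2428 and 1223 at DIV7, higher in replicate 1 on each of these days.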
